A study of Mus musculus with 5 samples.

How the data were processed

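RNA was measured in 5 libraries of cells sorted from the bone marrow of C57BL/6 mice aged 6 to 7 weeks. The sorted population was Hardy fraction A, the earliest fraction of the bone marrow B lineage in Hardy's scheme, taken without depleting other lineages. Of the libraries, 2 came from wild-type mice (wt), 2 from mice with a mutant Ikaros zinc finger 1 (dF1) and 1 from a mutant of zinc finger 4 (dF4), which the design text describes as having low coverage. The libraries were made from mRNA-enriched total RNA with Illumina TruSeq, per the labels' protocols. The design text calls the dF1 libraries biological replicates. The labels do not say whether the wt libraries came from separate mice, so p-values measure only the spread between these samples, which in wt may be technical. Xist and Y-linked transcripts show that the dF1 libraries came from mice of different sex.

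The deposited values are RPKM (reads per kilobase of transcript, scaled to the library total) for each RefSeq transcript, per the file headers, written to 1 decimal. The submitters' processing notes name TopHat, bedtools and the mouse build mm9, without versions. Aligner settings, strand use and the sharing of reads among transcripts and gene copies are not given in the sources used here. The table names transcripts by RefSeq identifier and gene symbol and gives their length but no position. The annotation supplied was of another build, so no coordinates are printed. The table held 26531 transcripts of 22098 symbols, of which 3305 had more than 1 transcript, and 1 further line that named no gene and was left out. No per-sample column was left unused.

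Several genes that every cell uses lay near 0 in every library. Gapdh was between 0.2 and 0.5 RPKM and Eno1 between 0 and 0.2, and Rpl27 and Rps23 were also low. These genes have many processed copies in the mouse genome. How reads were shared among copies is not given. The values of families with close copies of any kind (ribosomal proteins, some glycolytic enzymes, histones, Klra receptors, alpha and beta globins) are therefore uncertain. A value of 0 is given only as listed at 0. Without a stated strand, overlapping and antisense genes cannot be separated.

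Depth was looked for in the low values. In the dF4 library, values multiplied by transcript length were multiples of 1.68 RPM for 85.4% of 2326 low values (within 0.1 read), which puts the library at about 596000 reads. The step could not be resolved in the wt and dF1 libraries, and their depth is unknown. Rounding to 1 decimal may be coarser than 1 read there, which was not tested. Intervals printed for the dF4 library are exact 95% Poisson intervals on the reads so estimated, and cover counting error only.

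Differences were computed on log2(RPKM + 1), a scale that understates the change of low transcripts. The dF1 and wt libraries were compared, 2 against 2 and two-sided, with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) over the 12213 transcripts (11127 symbols) with a mean of at least 1 RPKM over the 5 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 3 members tested were compared by limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The 24 lists cover the Ikaros family, B lineage stages, progenitors, NK, T, dendritic, neutrophil, monocyte, basophil and mast, erythroid, megakaryocyte and stromal cells, Notch targets, adhesion, mitosis, DNA replication, interferon response, immediate early genes, glycolysis, ribosomal proteins and histones. A gene with several transcripts entered a list by the transcript with the highest mean.

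The dF4 library has no replicate and was described without a test. A transcript was counted as different when dF4 lay outside both wt libraries, the difference from the wt mean was at least 1 on the log2 scale, the wt libraries lay within 0.5 of each other and the mean over the 5 libraries was at least 5 RPKM. List medians of dF4 minus wt, and of dF4 minus dF1, were placed among 10000 random lists of the same size matched on mean expression in 20 bins. The dF1 and dF4 differences from wt share the wt libraries, so their correlation was set beside 100 simulations of unchanged groups.

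The lists, the tests, most alternatives and the rule for named genes were chosen before the data were examined. The Ikaros family is named first. For dF1, the rule takes the 10 largest changes in each direction past the threshold, or, where fewer pass, those with the smallest p whose dF1 libraries both lie on one side of both wt libraries. For dF4, it takes the 10 largest differences in each direction under the size rule, and from each list up to 4 members with the largest difference. Unnamed transcripts and small RNAs are not named.

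The alternatives were other pseudocounts (0.1 and 5), no filter or a higher one, quantile normalization, median centring, the replicate number as a block, a fit of all libraries, leaving out each replicate, eBayes with robust variances or without a trend, and other list tests. Taking 1 transcript per gene, the neutrophil level as a covariate, and describing the dF4 lists over all members in the table, whatever their level, were added after the data were seen. The tests were tried on simulated data first. Over 5 simulations of dF1 against wt with 12213 transcripts, 500 changes of 2-fold and 500 of 4-fold were made in total. The changed transcripts were drawn from those with a wt mean above 5 RPKM. Of these changes, 10.6% of 2-fold and 80.8% of 4-fold ones passed the threshold, with a mean of 4.2 false calls per simulation. In the list test, the shifted list was called in 5 of 5 simulations and 0 of 115 other lists were called. The simulated transcripts varied independently of each other. In the data the estimated correlation within lists ran from -0.062 (mature B and plasma cell) to 0.975 (neutrophil). The simulation therefore does not show how often lists of correlated members are called without a change. For the random-list description, 1 wt profile thinned to the dF4 depth with no change put 3 of 23 lists outside the middle 95%. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for depth and plots.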

Results

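The series measured transcript levels in Hardy fraction A cells of mouse bone marrow, to ask which hematopoietic lineages Ikaros affects and what its separate zinc fingers contribute. Ikaros, encoded by Ikzf1, is a zinc finger transcription factor of lymphoid development. The 5 libraries were 2 wt, 2 dF1 (zinc finger 1 mutant) and 1 dF4 (zinc finger 4 mutant). Summed over transcripts, the RPKM values came to 306100 and 286080 in the wt libraries, 298855 and 307910 in the dF1 libraries and 345446 in the dF4 library. Transcripts at 1 RPKM or more numbered 11884, 11887, 11667, 11880 and 12272 in the same order. The dF4 library held about 596000 reads, as estimated from its low values, and listed 13024 transcripts at 0, against 10492 to 11036 in the others.

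Ikzf1 was present in every library, at 175.8 and 141.1 RPKM in wt, 182.2 and 182.1 in dF1 and 237.7 in dF4. The value covers the whole transcript and does not resolve a single finger, so it does not check the genotypes. Ikzf1 did not pass the test between dF1 and wt (log2 fold change 0.21, SE 0.15, limma adjusted p = 0.827). Ikzf3, which encodes Aiolos, was at 42.5 ± 19 RPKM (SD, n = 2) in wt, 48.3 ± 4.24 (n = 2) in dF1 and 164.7 in dF4. Ikzf2 was at 5.5 RPKM in wt, 5.4 in dF1 and 13.9 in dF4, Ikzf5 lay between 2.8 and 4.6 in every library, and Ikzf4 was at 0.1 or below. Over the family's 4 tested members the median dF1 difference was 0.08 (camera adjusted p = 0.811), and the median dF4 difference was 0.89, at percentile 95.8 of matched random lists.

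The libraries also differed in ways that do not follow the groups. Xist, the RNA that silences an X chromosome in females, was at 77.7 and 83 RPKM in wt and 93.2 in dF1 replicate 1, and was listed at 0 in dF1 replicate 2 and dF4. The Y-linked Eif2s3y was at 37.5 RPKM in dF1 replicate 2 and 41.4 in dF4, and was listed at 0 in the other libraries. The neutrophil list was higher in replicate 2 than in replicate 1 for 21 of its 21 members in wt (median log2 difference 0.92) and for 21 of 21 in dF1 (median 1.74). The erythroid list was also higher in replicate 2, for 16 of 19 members in wt and 18 of 19 in dF1 (median 0.86 in both). The NK cell list was lower in wt replicate 2 than in wt replicate 1, with a median of -1. Across transcripts, the correlation was 0.977 between the wt libraries, 0.981 between the dF1 libraries and 0.965 to 0.983 between wt and dF1 libraries. The closest pair was wt replicate 1 and dF1 replicate 1 (0.983), so wt and dF1 libraries did not group by genotype in this measure. Between dF4 and the others it was 0.74 to 0.774.

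**Figure D1:**
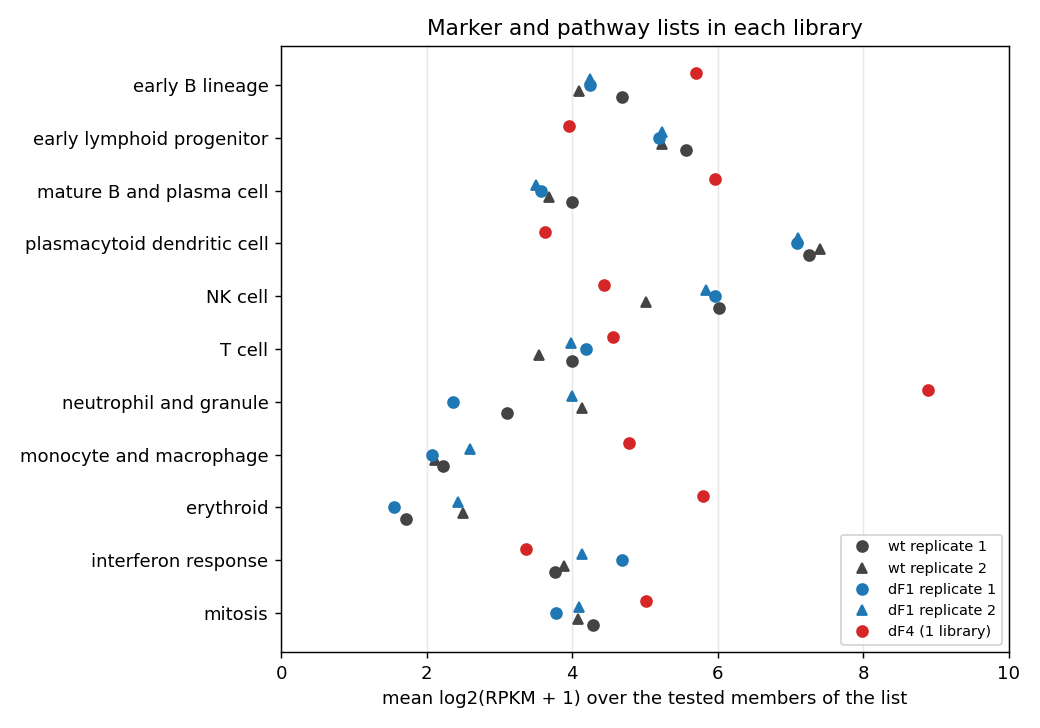
Mean log2(RPKM + 1) of the tested members of 11 marker and pathway lists (horizontal axis) in each of the 5 libraries, colored by group, with circles for replicate 1 and the dF4 library and triangles for replicate 2. The dF4 library stands apart, with its plasmacytoid dendritic cell list at 3.62 against 7.09 to 7.41 in the other libraries and its neutrophil list at 8.89 against 2.36 to 4.13.

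The first comparison asked how the dF1 mutation changes the transcripts of fraction A cells. Among the transcripts closest to the threshold, Clec9a (NM_001205363), a lectin receptor of cross-presenting dendritic cells, was at 37 ± 0.636 RPKM (SD, n = 2) in wt and 10.9 ± 0.566 (n = 2) in dF1. Blk, a Src family kinase of B cells, was at 35.2 ± 0.919 RPKM in wt and 14.1 ± 0.424 in dF1. Cd8a (NM_001081110), a T cell co-receptor that some dendritic cells also carry, was at 26.7 ± 1.56 RPKM in wt and 112.8 ± 25.7 in dF1. Cd36, a fatty acid receptor, was at 1.45 ± 0.0707 RPKM in wt and 12.1 ± 2.9 in dF1. None of these differences passed the correction for multiple tests, with an adjusted p of 0.126 for each.

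Over 12213 transcripts limma called 0 higher and 0 lower in dF1 at adjusted p 0.05. At an unadjusted p under 0.05 there were 875 (380 higher and 495 lower), where chance gives 611. The dF1 and wt ranges did not overlap for 34.7% of transcripts, where chance gives 33.3% for 2 against 2. The outcome depended on the setting. Testing only the 8759 transcripts with a mean of at least 5 RPKM called 25 (13 higher and 12 lower), and robust variances called 33 (16 higher and 17 lower), with 22 shared by both.

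The other transcripts that the naming rule takes as higher in dF1 were Hfe, a regulator of iron uptake (0.55 ± 0.0707 RPKM in wt and 9.3 ± 1.56 in dF1, log2 fold change 2.72, SE 0.18), Slc7a6os (26.3 ± 0.778 and 68.8 ± 0.566), Podnl1 (0.65 and 8.95), Hsd3b7, an enzyme of bile acid synthesis (8.25 and 24.6), the phosphoglycerate mutase Pgam2 (19.2 and 56.1), Dkkl1 (4.05 and 26.3), Avil (0.1 and 3.25) and the hormone precursor Sct (1.1 and 9.35). Those lower in dF1 were the linker histone H1f0 (32.8 ± 4.38 RPKM in wt and 7.2 ± 0.566 in dF1, log2 fold change -2.04, SE 0.15), the myosin Myo7a (7.3 and 1.55), the kinase subunit Camk2b (8 and 0.8), Sdc1, a surface proteoglycan of plasma cells (14.1 and 5.35), the growth factor Pdgfa (5.4 and 0.7), the phosphatase Inppl1 (19.8 and 8.75), the focal adhesion protein Tns1 (43.1 and 17.8) and Nfe2l3 (3.6 and 0.85). Their adjusted p lay between 0.126 and 0.194. Of the 20 named, 13 were tested and 13 called with the filter at 5 RPKM, and 19 were called with robust variances, all but Nfe2l3. The 20 were picked for their small p in these same libraries, so these calls are not an independent check.

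**Figure D2:**
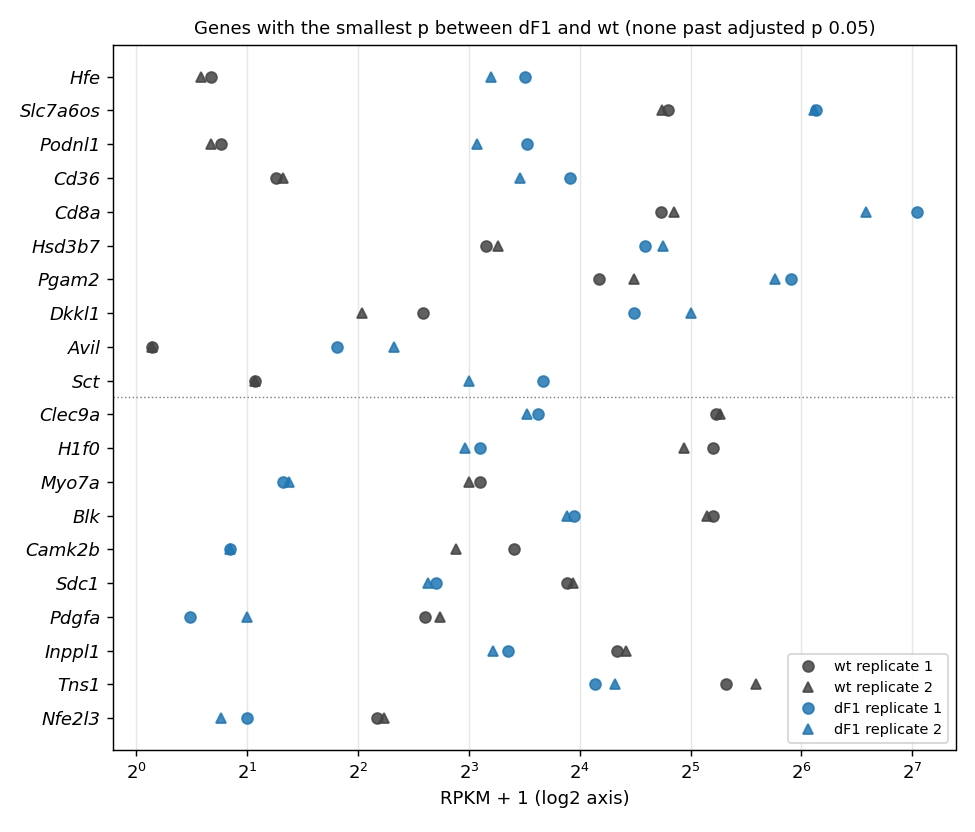
RPKM + 1 on a log2 axis of the 20 transcripts named for dF1 against wt, with a point for each of the 2 wt (grey) and 2 dF1 (blue) libraries, circles for replicate 1 and triangles for replicate 2. The naming rule requires that both dF1 libraries lie on one side of both wt libraries for each transcript. The smallest adjusted p was 0.126.

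Among the gene lists, the interferon response list rose in dF1. Of its 25 members 23 were higher, with a median log2 fold change of 0.48 (camera adjusted p = 6.79e-09, and adjusted p = 0.882 with an estimated correlation). None of its members (0 of 25) passed over all transcripts or adjusted over the list alone. Ifit3 was at 0.6 and 0.7 RPKM in wt and 5 and 2.1 in dF1, Ifit1 at 1.5 and 1.3 against 6.8 and 3.1, and Oas3 at 3 and 4 against 11 and 7.5. The list was lower in dF1 replicate 2 than in dF1 replicate 1 (median -0.65). The mitosis list fell, with 21 of 22 members lower and a median of -0.26 (adjusted p = 4.62e-05, and adjusted p = 0.882 with an estimated correlation). Its Aurka, a mitotic kinase, was at 15.7 and 13.4 RPKM in wt and 9.5 and 12 in dF1. Without dF1 replicate 1 the mitosis call was lost (median -0.11, adjusted p = 0.124), and the interferon median was 0.26, against 0.85 without dF1 replicate 2, with the call kept in both cases. Of the 24 lists 9 passed, none of which kept its call with an estimated correlation, and fry called 0 lists for a shift in one direction. For changes in either direction fry called 7 lists, namely mature B and plasma cell (adjusted p = 0.00531), early B lineage, early lymphoid progenitor and conventional dendritic cell (0.0174 each), Notch target (0.0239), stem (0.034) and immediate early (0.0491).

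Lymphoid lists went both ways. The NK cell list rose, with 23 of 26 members higher and a median of 0.55 (adjusted p = 0.000378, and adjusted p = 0.882 with an estimated correlation). Gzma, a granule protease, was at 356.2 and 195.5 RPKM in wt and 634.1 and 504.2 in dF1, whereas the Ly49 receptor Klra4, which has close copies, was at 39.8 and 14.4 in wt and 8.3 and 5.8 in dF1. Without wt replicate 2 the NK median was 0.05 and the call was lost (adjusted p = 0.657). Without dF1 replicate 1 the call was also lost (0.124) but the median stayed at 0.54, and without wt replicate 1 it was 1.03. The T cell list also rose (16 of 20 higher, median 0.30, adjusted p = 0.00875, and adjusted p = 0.882 with an estimated correlation) and lost its call without wt replicate 2 (median -0.02, 0.534) and without dF1 replicate 1 (0.34). The T cell call was also lost with no filter (adjusted p = 0.0708) and with the neutrophil level of each library as a covariate (median 0.19, adjusted p = 0.067), a setting chosen after the data were seen. Adjusted over the list alone, Cd8a, Cd4 and Cd3e were higher and Cd6 was lower, and 0 passed over all transcripts. Cd4, a co-receptor also found on plasmacytoid dendritic cells, was at 150.2 ± 5.52 RPKM (SD, n = 2) in wt and 329 ± 80 (n = 2) in dF1.

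The plasmacytoid dendritic cell (pDC) list fell slightly, with 15 of 21 members lower and a median of -0.14 (adjusted p = 0.00931, and adjusted p = 0.882 with an estimated correlation). In the wt libraries its mean log2(RPKM + 1) was 7.25 and 7.41, against 4.68 and 4.09 for the early B lineage list. Which cells of the sort held the changed transcripts was not tested. Siglech, a pDC surface lectin, was at 887.3 ± 69.2 RPKM (SD, n = 2) in wt and 796.2 ± 15.6 (n = 2) in dF1. Cox6a2 was at 246 and 392.1 in wt and 141.9 and 206 in dF1. The call was lost without wt replicate 2 (median -0.09, adjusted p = 0.217), without dF1 replicate 2 (0.165) and with no filter (0.0708). The mature B and plasma cell list fell, with 9 of 14 members lower and a median of -0.15 (adjusted p = 0.0293, and adjusted p = 0.882 with an estimated correlation). Adjusted over the list alone, 3 members passed, Sdc1, the B cell receptor inhibitor Cd22 and 2010001M09Rik (also called Mzb1), and leaving out any replicate ended the call. The median was then -0.24 without wt replicate 2 (adjusted p = 0.0547), -0.13 without wt replicate 1 (0.0583), -0.32 without dF1 replicate 2 (0.108) and -0.05 without dF1 replicate 1 (0.131). Camera on ranks (0.162) and no filter (0.12) also ended it. The early lymphoid progenitor list fell, with 9 of 15 members lower and a median of -0.11 (adjusted p = 0.0293, and adjusted p = 0.882 with an estimated correlation). Of its members, Arpp21 passed adjusted over the list alone. Ly6d, a marker of B-biased progenitors also in the pDC list, was at 1046 ± 188 RPKM in wt and 534.5 ± 65.3 in dF1. This call was lost without wt replicate 1 (median -0.15, adjusted p = 0.581), without dF1 replicate 1 (-0.03, 0.124), with camera on ranks (0.111), with no filter (0.0708) and with the filter at 5 RPKM (-0.03, 0.102), while the median was -0.3 without wt replicate 2 and -0.23 without dF1 replicate 2.

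The early B lineage list did not pass (median -0.06, adjusted p = 0.121), and of its 25 members Blk alone passed adjusted over the list alone. The neutrophil list, which differed between replicates of 1 genotype, did not pass (median -0.56, 0.121), nor did the monocyte list (0.20, 0.115), the stem and multipotent progenitor list (-0.17, 0.293) or the erythroid list (-0.11, 0.527). Leaving out a single library changed this for several lists, in fits of 2 libraries against 1 whose spread comes only from the group of 2. The early B lineage list passed without wt replicate 2 (-0.36, 0.000163), the neutrophil list without wt replicate 1 (-1.07, 0.0095) or dF1 replicate 2 (-1.48, 1.4e-05), and the monocyte list without wt replicate 2 (0.10, 0.048) or dF1 replicate 1 (0.45, 0.000529). The erythroid list passed as lower without wt replicate 1 (-0.61, 0.00507) or dF1 replicate 2 (-0.43, 0.0409) and as higher without wt replicate 2 (0.28, 0.028). Over all 4 libraries, the early B lineage list passed with the filter at 5 RPKM (0.0392) and with the neutrophil covariate (0.0256). The neutrophil list passed with camera on ranks (0.0334), and the monocyte list after quantile normalization (0.0324) and with the covariate (0.00643). With the replicate number as a block, the neutrophil list passed as lower (-0.56, 5.63e-06), the erythroid list as lower (-0.11, 0.0407) and the monocyte list as higher (0.20, 0.0407). The conventional dendritic cell and MHC class II list did not pass either (0.07, 0.676), and Clec9a was its member lower in dF1 when adjusted over the list alone. The Notch target list was at 0.11 (0.621) and the DNA replication list at 0.04 (0.802), and 0 of their members passed.

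The second comparison set the single dF4 library beside wt. Most transcripts of the pDC list were far lower in it. Siglech (NM_178706) was at 5.5 RPKM (95% Poisson interval 2.41 to 11, about 8 reads), 161-fold below the wt mean of 887.3 RPKM, and Cd300c was listed at 0 against 211.4 in wt. S100a9, a calcium-binding protein of neutrophils, was at 14100 RPKM (13700 to 14500) in dF4 and 148.5 and 350.6 in wt. There is no replicate of dF4 and hence no test.

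By the size rule 610 transcripts were higher and 818 lower in the dF4 library than in wt, of 8759 considered. Of these, 7867 had wt libraries within 0.5 of each other and could be counted. The mean of at least 5 RPKM includes dF4, so transcripts near 0 elsewhere entered only by being high in dF4, as Il9r did. The counts higher and lower are therefore not on an equal footing. When the wt profile was thinned to the depth of dF4, the median over 100 draws was 23 higher (at most 37) and 82 lower (at most 114). Among the transcripts that met this rule, the largest differences upward were the neutrophil serine proteases Prtn3 (335.9 RPKM in dF4 and 4.15 in wt) and Ctsg (309.8 and 3.8), Faim3 of mature B cells (198 and 2.5), the acute phase protein Orm1 (56.9 and 0.25), Eif2s3y, Tgfbi (129.5 and 2.1), the chemokine Cxcl12 (62.6 and 0.7), Ms4a1, which encodes CD20 (80.9 and 1.4), Il9r (34.1 and 0.1) and Ms4a3 of myeloid precursors (64.2 and 1.2). Downward, beside Cd300c, Siglech and Xist, they were the integrin Itgax (0.4 RPKM, about 1 read, in dF4 and 108.5 in wt), Havcr1 (listed at 0 and 71.1), the chemokine receptor Ccr9 (1.9 and 130.4), Prss30 (listed at 0 and 43.3), the lysosomal protease Ctsl (7.6 and 319), Cd4 (3.2 and 150.2) and the cadherin Cdh1 (0.4, about 1 read, and 46.6). Transcripts whose wt libraries lay further apart than the rule allows were not ranked, among them Cox6a2, listed at 0 in dF4 against 246 and 392.1 RPKM in wt, and the elastase Elane, at 537.8 against 4.7 and 9.4.

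Of the 21 pDC members, 21 were lower in dF4, with a median log2 difference of -3.18, at percentile 0 of matched random lists, and 16 of 20 counted as lower by the size rule. Not all were near 0, as Ly6d was at 311.8 RPKM in dF4 against 1046 in wt, the transcription factors Irf8 at 215.8 against 1254 and Spib at 155.7 against 339, Tlr9 at 47.8 against 80.8 and Cadm1 at 3.1 against 3.8. The early lymphoid progenitor list was also lower (11 of 15, median -1.12, percentile 0), led by Ccr9, by Flt3, a cytokine receptor of early progenitors and dendritic cells (5.5 RPKM in dF4 and 139.6 in wt), and by Dntt, which encodes the terminal transferase (14.8 and 195.7). The pDC and early lymphoid lists share Ccr9 and Ly6d. In the same list Il7r was at 51.3 RPKM in dF4 and 92.6 in wt, and Rag1 at 16.6 and 21.4. The NK cell list was lower for 22 of 26 members (median -0.79, percentile 0), with Gzma at 73.6 RPKM, but without wt replicate 1 its median was -0.21, at percentile 5.45 and within the middle 95%. The interferon response list had a median of -0.66 (percentile 0.04) over 14 lower and 11 higher members, led by Bst2, which also marks pDCs (110.3 RPKM in dF4 and 1145 in wt), while Oas3 was at 25.8 against 3.5 in wt.

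Myeloid and erythroid lists were higher in the dF4 library. For the neutrophil list 21 of 21 members were higher, with a median of 5.25 (percentile 100), including Elane at 537.8 RPKM against 7.05 in wt. By the size rule 3 of its 20 members counted, because the wt libraries differ in most of them. The monocyte list was higher for 18 of 20 members (median 2.83, percentile 100), with the lysozyme Lyz2 at 1124.3 RPKM against 37 in wt, and the erythroid list for 18 of 19 (median 3.90, percentile 100), with the anion exchanger Slc4a1 at 327.2 RPKM against 1.6 and 13.5 in wt. By the size rule 0 of 12 erythroid members counted as higher and 1 as lower.

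B lineage lists were higher as well. Of the early B lineage list 21 of 25 members were higher (median 1.35, percentile 100), among them Pou2af1 (169 RPKM in dF4 and 14.1 in wt), Pax5, the B lineage commitment factor (61.5 and 6.6), and Blk (89.8 and 35.2). Of the mature B and plasma cell list 12 of 14 were higher (median 1.41, percentile 100), with Cd40 at 40.5 RPKM against 0.75. The T cell list was higher for 15 of 20 members (median 0.89, percentile 99.99), with Cd3d at 115.5 RPKM against 20.1 and Cd4 going the other way. The conventional dendritic cell and MHC class II list had a median of 1.65 (percentile 100) with members in both directions, H2-Aa at 1140.3 RPKM against 406 and 325.7 in wt and Itgax and Clec9a lower. The mitosis list was higher for 20 of 22 members (median 0.92, percentile 100), with Mki67 at 146 RPKM against 58.2, and the DNA replication list for 20 of 23 (median 0.47, percentile 99.68). The stem and multipotent progenitor list (-0.47, percentile 3.56) and the Notch target list (-0.62, percentile 4.54) lay within the middle 95% of random lists. Over all members in the table, low ones included, the stem list had a median of 0.28 (20 members, percentile 84.28) and the Notch list -0.58 (11 members, percentile 0.61), and the dendritic cell and MHC class II median was 1.08.

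**Figure D3:**
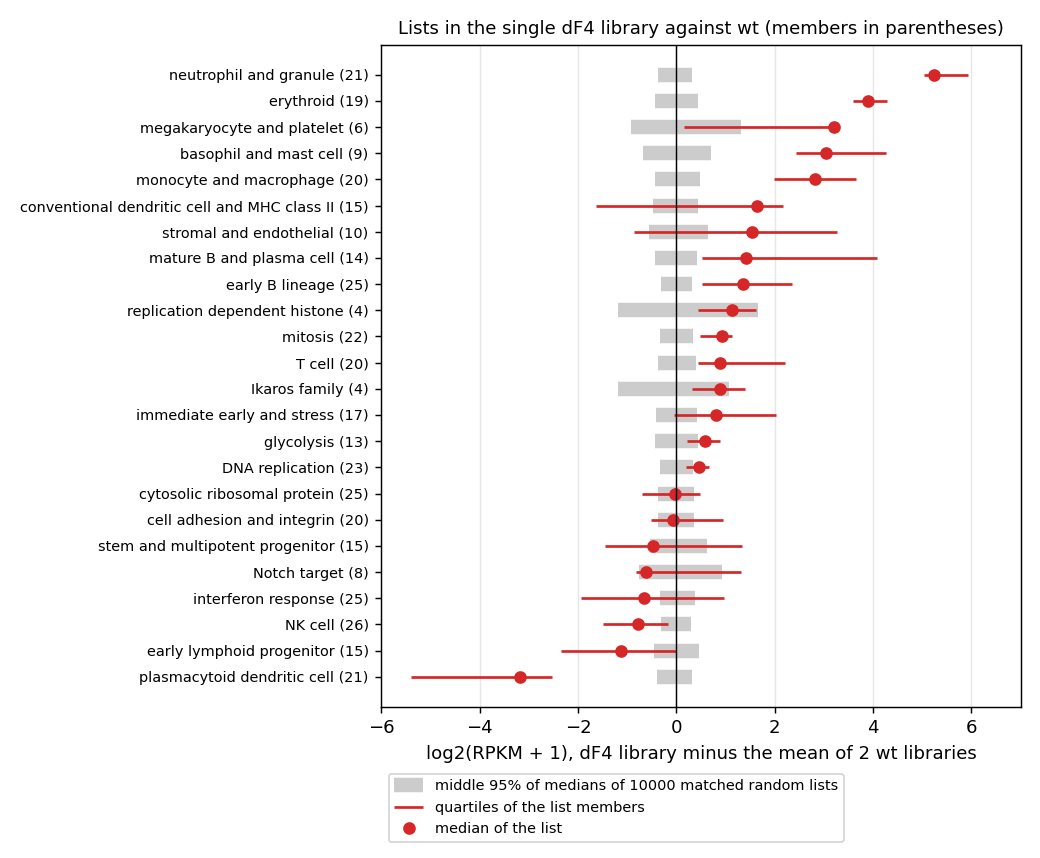
Median difference of log2(RPKM + 1) between the dF4 library and the mean of 2 wt libraries for each of 24 gene lists (red points, with lines for the quartiles of the members), beside the middle 95% of medians of 10000 matched random lists (grey bars). The pDC list lies lowest at -3.18 and the neutrophil list highest at 5.25.

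Set directly against the dF1 libraries, the dF4 library lay outside the middle 95% of random lists for 17 lists, against 18 when set against wt. In a wt profile thinned to the dF4 depth, with no change made, 3 of 23 lists also lay outside it. The pDC list was lower for 20 of 21 members (median -3.19, percentile 0) and the NK cell list for 25 of 26 (median -1.39, percentile 0). The neutrophil list was higher for 21 of 21 (median 5.77, percentile 100), the erythroid list for 18 of 19 (median 4.04), the early B lineage list for 20 of 25 (median 1.82), the mature B and plasma cell list for 12 of 14 (median 2.18) and the mitosis list for 22 of 22 (median 1.13). The interferon response list had a median of -0.95 (percentile 0), with 19 of 25 members lower. Of the 20 transcripts named for dF1, 12 differed from wt in the same direction in dF4 (7 by at least 1 on the log2 scale) and 8 in the opposite one (3 by at least 1), with the wt libraries shared. Some of these rest on few dF4 reads, about 1 for Pdgfa, 3 for Podnl1 and 5 for Hfe in the same direction. In the opposite direction, Dkkl1 and Sct were listed at 0, where 3 reads are worth 5.54 and 9.85 RPKM. Cd36 was at 19.8 RPKM in dF4 (12.1 in dF1 and 1.45 in wt), Clec9a at 2.5 (10.9 and 37) and Tns1 at 2.8 (17.8 and 43.1), whereas Cd8a was at 22.6 RPKM in dF4, near the wt mean of 26.7, and H1f0 was at 49.8 against 32.8 in wt and 7.2 in dF1.

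Across 8759 transcripts, which are not independent replicates, the dF1 and dF4 differences from wt correlated at r = 0.147, with a covariance of 0.0459. Unchanged groups sharing the wt libraries gave a mean r of 0.21 (0.168 to 0.258) and a mean covariance of 0.0185 (0.0147 to 0.022), which leaves a covariance of 0.0274. The simulated transcripts varied independently of each other, so this remainder does not isolate a shared effect of the mutations. The correlation was -0.04 without dF1 replicate 2 and 0.294 without dF1 replicate 1. With a different wt library for each mutant the correlation was 0.132 (covariance 0.0397) or -0.013 (covariance -0.00544), so both depended on which libraries entered.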

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

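The 1-transcript-per-gene setting, the neutrophil covariate and the dF4 lists over all members were chosen after the data were seen. The count of 0 transcripts called between dF1 and wt held under other pseudocounts, no filter, both scalings, a fit of all libraries, no trend and 1 transcript per gene. It was also 0 with the neutrophil covariate. A fit with that covariate, with the replicate block or without 1 replicate leaves 1 residual degree of freedom, so it cannot show whether the count holds. The count became 25 with the filter at 5 RPKM and 33 with robust variances, and the cause was not tested. The smallest adjusted p went from 0.126 to 0.0174 with that filter and to 0.00711 with robust variances. Without a call, it came to 0.0509 after median centring, 0.079 after quantile normalization and 0.0953 with 1 transcript per gene. It lay between 0.122 and 0.194 with the other pseudocounts, no filter, a fit of all libraries and no trend. The count at an unadjusted p under 0.05, 875, was 1527 with no filter (17460 transcripts tested, the cause not tested further) and ranged from 515 without wt replicate 2 to 1441 without wt replicate 1. The 9 lists called became 0 with an estimated correlation, 0 with directional fry (7 lists with fry for either direction) and 3 with no filter, and ranged from 3 without dF1 replicate 1 to 10 without wt replicate 1. The ribosomal list median turned to -0.2 without wt replicate 2 and was at most 0.74, without wt replicate 1, and the cause was not tested. The titles number the replicates 1 and 2 in wt and dF1, and the labels do not say that a number marks a shared day. Replicate differences correlated between the groups at r = 0.305 across transcripts, over only 2 pairs. With the replicate number as a block, limma called 0 transcripts, 1071 had an unadjusted p under 0.05, and 13 lists were called.

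For dF4 against wt, 818 lower became 533 with a pseudocount of 5, and 610 higher and 818 lower became 1287 and 1306 with the filter at 1 RPKM and 170 and 361 at 20 RPKM, and the cause was not tested. A limma contrast with pooled spread, which assumes that the lone dF4 library varies like the others, gave 1560 higher and 1743 lower. Without a wt replicate the counts were 769 to 992 higher and 935 to 1010 lower, since the limit on the wt gap no longer applied. The correlation of 0.147 was 0.133 and 0.153 with pseudocounts of 0.1 and 5, 0.13 and 0.143 with filters at 1 and 20 RPKM, 0.18 after quantile normalization, and -0.04 to 0.294 without single replicates, and the cause was not tested. Of 18 lists outside the middle 95% of random lists against wt, 18 to 18 lay there without a wt replicate, where without wt replicate 1 the NK list left (-0.21, percentile 5.45) and the ribosomal list entered (0.48, percentile 98.04), and 17 to 17 against dF1. Over all members these counts were 20 and 19. For 110 transcripts (the 20 named for dF1 and the leading members of each list), 1678 values under alternatives kept their direction and side of the threshold, 33 passed it and 21 changed sign without a call. For 80 transcripts in dF4, 490 values stayed within 0.5 of the main difference and 114 moved further. For the 24 dF1 lists 287 values kept the test's direction and side, 48 lost the call, 21 gained one in the same direction, 25 changed the test's direction from no call (1 of them, erythroid without wt replicate 2, to a call) and 1 reversed. Of the dF4 list medians, 124 against wt stayed within 0.5 and 18 moved further, and 125 and 17 against dF1. Low depth limits the dF4 values, where 3 reads are worth 2.09 RPKM for Siglech and 7.25 for Cd300c.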

Other observations

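Smaller groups also differed in the dF4 library. Basophil and mast cell transcripts were higher for 7 of 9 members (median log2 difference 3.05, percentile 100) and had a median of 2.29 over all 15 members in the table, with the basophil proteases Mcpt8 at 146 RPKM against 2 in wt and Prss34 at 274.2 against 4.6. Of 6 megakaryocyte transcripts with a mean of at least 1 RPKM 4 were higher (median 3.20, percentile 99.99), among them the platelet chemokine Pf4 at 19.9 RPKM (about 7 reads) against 0.2, which reached that mean through dF4. Over all 16 members 10 were higher and the median was 0.83 (percentile 99.8). The stromal and endothelial list had a median of 1.54 (percentile 99.99; 1.36 over all 16 members), led by Cxcl12, and was at 0.86 without wt replicate 1. Immediate early genes were at 0.80 (percentile 99.93) and glycolysis at 0.59 (percentile 99.44). The ribosomal protein list (-0.02, percentile 44.87), the adhesion list (-0.07, percentile 34.85) and the histone list (1.13 over 4 members, percentile 91.89) lay within the middle 95% of random lists, and over all 24 histone members the median was 0 (percentile 2.26). Without wt replicate 1 the immediate early median was 1.43 and the ribosomal median 0.48 (percentile 98.04).

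Between dF1 and wt, the glycolysis list rose (median 0.27, 11 of 13 higher, camera adjusted p = 0.0293) and the ribosomal protein list rose (0.39, 22 of 25 higher, 0.0424), both with an adjusted p = 0.882 with an estimated correlation. Without wt replicate 2 the glycolysis median was 0.06 (adjusted p = 0.0927) and the ribosomal median turned to -0.2 (0.217), and without dF1 replicate 1 they were 0.26 (0.131) and 0.28 (0.619). Both calls were also lost with no filter (0.095 and 0.12) and with the neutrophil covariate (0.0507 and 0.177), glycolysis without dF1 replicate 2 (0.169) and ribosomal proteins with a pseudocount of 5 (0.0526). The basophil and mast cell list did not pass (0.06, 0.217), although the mast cell chymase Cma1 was at 3 RPKM in wt and 27.2 in dF1 and passed adjusted over the list alone. Histones (-0.29, 0.0991, with 4 of 24 members tested), adhesion (0.14, 0.159), immediate early genes (-0.11, 0.564), stromal cells (-0.42, 0.676) and megakaryocytes (-0.07, 0.799) did not pass. With the replicate number as a block the histone list did pass (-0.29, 0.0407). The basophil list passed without wt replicate 2 (0.21, 0.0184), the stromal list without wt replicate 1 (-0.45, 0.0213) and the histone list without dF1 replicate 2 (-0.53, 0.0421), and with the neutrophil covariate the basophil (0.21, 0.00687) and immediate early lists (-0.13, 0.0104) passed. Over the 24 lists 17 members passed adjusted over the list alone, 8 higher and 9 lower. Those not named with their list above were Cd34 of the stem list (log2 fold change 1.06, adjusted p = 0.0197 over the list alone), the endothelial cadherin Cdh5 (0.72, 0.0446), Ier3 and Actn1, which were higher in dF1, and Pecam1 (-0.5, 0.0446) and Tns1, which were lower. Ier3 belongs to the immediate early list, where 7 members were higher and 10 lower. Its largest differences were downward. Fos was at 59.5 and 19.9 RPKM in wt and 12.9 and 2.7 in dF1, and Jun at 28.1 and 13.5 against 9.8 and 2.6. Neither Fos nor Jun passed adjusted over the list alone.

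The tests below were chosen after the main results were seen, and for the neutrophil covariate, the splits of the 4 libraries and the odds ratio the bounds were set before their own values were seen. In the dF4 library the pDC list was lower by a median of -3.18. The tables argue against low depth, since the lowest list median over 100 wt profiles thinned to the dF4 depth was -0.05. Dilution of the whole sort by cells that hold none of their transcripts would lower the pDC, NK and early B lists alike. The pDC median lay -2.39 from the NK median, and the upper quartile of the pDC list (-2.53) was below the lower quartile of the NK list (-1.50). The early B median was 1.35. These values argue against that simple dilution only. Dilution by cells that hold NK or B lineage transcripts was not tested, and without wt replicate 1 the NK median was -0.21. A sex difference stays open, because the only other library with Y-linked transcripts, dF1 replicate 2, had a pDC list 0.06 above that of dF1 replicate 1 but is 1 library. Loss of zinc finger 4 may also be the cause and cannot be told apart from a different sort, since there is 1 dF4 library.

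The neutrophil list was higher by a median of 5.25 in the same library, with S100a9 at 14100 RPKM and S100a8 at 5891. Low depth gave at most 0.34 over 100 thinned wt profiles. Neutrophils carried into the sort are a candidate source, as the fraction was sorted without depleting other lineages and 21 of 21 members were also higher in wt replicate 2 than in wt replicate 1, with no difference of genotype. None of the neutrophil members stands in another list. A genotype effect on myeloid cells stays open with 1 dF4 library.

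No transcript passed the threshold between dF1 and wt, while 875 had an unadjusted p under 0.05. The number of libraries could account for missed 2-fold changes, of which 10.6% were called in simulation, while 80.8% of 4-fold changes were called, too close to the bound of 80% set for that test to decide. With the neutrophil level as a covariate 0 transcripts passed, which decides nothing because the covariate takes 1 of the 2 residual degrees of freedom. The 3 splits of the 4 libraries are too few for a share under 0.05, with 1 split (the real one) at 875 or more and the highest other, replicates 1 against 2, at 740. Transcripts lower in dF4 had higher odds of an unadjusted p under 0.05 at equal wt level (odds ratio 2.74, 95% interval 2.27 to 3.31), but so did those higher in dF4 (3.03, 2.43 to 3.78), and odds above 1 also arose between replicates 2 and 1 of the same genotypes (1.36, 0.97 to 1.9, for lower and 1.92, 1.3 to 2.82, for higher), so the odds ratio decides nothing about cells that dF4 lacks.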
